A study of Mus musculus with 2 samples.

How the data were processed

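RNA from mouse spleen, wild type or labelled Loxl3 knockout, was hybridised to 2 one-colour Agilent arrays, 1 per group. Per the labels' protocols, total RNA was extracted from fresh spleens of untreated males, cleaned on columns and labelled with Cy3. Groups were taken from the genotype in the labels. Whether RNA of several animals was pooled is not stated in the sources used here.

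The deposited scanner files hold linear intensity values per spot. Per the file headers they were made with Feature Extraction 11.0.1.1 under the protocol GE1_1100_Jul11, with probe positions on the genome build mm9, and the submitters' processing notes also name Agilent Feature Extraction. The processed signal is the background-corrected intensity, per the file headers, and comes with an error per spot from the same software. Both arrays lay on 1 slide and were scanned together, per the file headers, so slide and scan do not differ between the groups. The authors' deposited value table is on a log2 scale, with both columns at a median of 6.71. Set against the scanner files, its rows matched as log2 processed signals quantile-normalized between the arrays, and 3 of 39420 shared probes had a difference over 1 from the scanner difference. The processing text behind that table was not used here, so its steps are read from its values.

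Each array had 44397 spots, of which 1377 were controls (153 of them negative controls) and 43020 were used. Spots flagged as outliers by the software were left out, 110 on the wild-type array and 132 on the knockout-labelled array, and no spot was saturated on either. Log2 processed signals of the remaining spots of a probe were averaged, which left 39420 of 39429 probes. Each array's 75th percentile, a signal of 974 on the wild-type array and 1400 on the knockout-labelled array, was subtracted on the log2 scale, a shift of 0.52 between them. The files name probes by accession. The accessions were matched, without versions, to RefSeq transcripts of the assembly GRCm38.p6, which named 27226 probes (20655 genes) and left 12194 without a symbol. The array's build differs from that assembly, so no coordinates are given and the table served only for names and the order of neighbouring genes.

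A gene was represented by its brightest probe among probes well above background, by the software's own call, on at least 1 array, which gave 13716 genes, 13034 of them above background on both. Differences are log2 values of the knockout-labelled minus the wild-type array. A gene above background on 1 array alone has only a bound, taken as the bright array's scaled signal over the higher of the dim probe's own and the lowest signal among probes well above background on the dim array, and written as "at least". Counts of 2-fold genes include 117 higher and 76 lower genes above background on 1 array alone, of which 55 and 37 have a bound of 2-fold or more.

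With 1 array per group there are 0 residual degrees of freedom, so no p-value was computed. The errors at hand are technical. For 272 probes printed 10 times and above background, with 2610 spots, the log2 difference between the arrays had a median SD of 0.119 over repeated spots (90th percentile 0.271), and the software's error of the log2 difference had a median of 0.205 over genes. The number of arrays limits the precision of every value.

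The counts of genes at 2-fold, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The 32 lists were the lysyl oxidase family, STAT3 pathway and target genes, Th17, regulatory T, and Th1 and Th2 cell genes, germinal centre genes, extracellular matrix and fibroblast genes, lymphoid stromal chemokines, proliferation, interferon-stimulated and immediate early genes, cytokines and chemokines of inflammation, heat shock and unfolded protein response genes, lysine deacetylases, ribosomal protein, housekeeping and sex-linked genes, and markers of T cells, B cells, plasma cells, NK and cytotoxic cells, macrophages, monocytes, dendritic cells, neutrophils and granulocyte precursors, mast cells and basophils, erythroid cells, megakaryocytes and platelets, smooth muscle, endothelium, pancreas, and adipose tissue and mesothelium. They held 458 genes under current symbols, of which 447 had a probe and 415 were measured. A list's median log2 difference was placed among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these 2 arrays, and a list stood apart outside their central 95%. Further lists for the closing tests (further acinar, islet, haematopoietic progenitor, neutrophil precursor and mature blood neutrophil genes) were written after the main results were seen.

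Genes were named by a fixed rule. It takes the lysyl oxidase family, the 10 largest differences in each direction among genes at 2-fold, above background on both arrays and with all detected probes of 1 sign, the 5 largest bounds in each direction among genes above background on 1 array alone, and up to 4 members of each list with the largest absolute difference, plus members needed to describe a count. Symbols of clone or predicted-gene type were left out of the rankings. Any gene named beyond this was chosen after its values were seen.

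Alternatives were scaling to the array median, quantile normalization, removal of a loess trend of the difference on signal (fraction 0.3), normexp background correction (offset 50), the deposited value table, other filters on dim probes, other rules for several probes per gene, other thresholds, lists without shared members, and random lists not matched on signal. Normexp was planned on mean signals and was run on the median signals, because the scanner files hold no mean signal column. Added after seeing the data were scaling on probes above background on both arrays, counts without the pancreas, further acinar and islet lists or without blood cell genes, and genes with 2 or more probes all passing 2-fold.

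The calculation was tested on simulated data of this comparison, with known differences put into 200 genes, of which 194 were among the 13227 genes in the step. Of genes with a log2 difference of 1.5 put in, 95.9% were called higher (49 genes), and of those with −1.5, 100% were called lower (50 genes). All 48 and 47 genes at 3 and −3 were called. Among 13014 unchanged genes 0.415% passed 2-fold. The simulated array drew its error from repeated spots above background on both arrays, without a trend on signal level. It took the wild-type array's background calls, so these rates do not cover genes above background on 1 array alone. A list of 19 genes shifted by 0.5 lay at percentile 100, and 5% of 200 unshifted lists stood apart. Error was drawn independently for each probe, so that share does not cover lists whose genes move together. Arrays were read with R 4.3.3, limma 3.58.1 and the data.table package, version 1.17.8, and calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with plots in matplotlib 3.10.9.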

Results

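Gene expression in the spleen of male mice was measured on 2 one-colour microarrays, 1 hybridised with RNA from wild-type spleen and 1 with RNA from spleen labelled Loxl3 knockout. The labels describe the animals as healthy and untreated, and they do not state whether RNA of several animals was pooled. The comparison asks which spleen genes differ with the Loxl3 genotype. Loxl3 encodes a member of the lysyl oxidase family, copper-dependent enzymes known for crosslinking collagen and elastin, and it has been described as acting on the transcription factor STAT3 in T cells. The median probe signal was 84.8 on the wild-type array and 130 on the knockout-labelled array, with negative control spots averaging 11.5 and 14.9. On these arrays 21572 probes (54.7%) and 22389 probes (56.8%), in that order, were well above background. With 1 array per group no difference below has a replicate check, and all values describe these 2 arrays. Errors written after ± are those the scanner software gave per spot, carried to the log2 difference, and they hold no variation between animals.

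The Loxl3 probe was not clearly lower on the array labelled knockout. Its signal was 117 on the wild-type array and 125 on the knockout-labelled array, a scaled log2 difference of −0.43 ± 0.29, or 0.743 times the wild-type level. Whether this single probe lies inside the deleted part of the gene is not given in the sources used here, so the value is no firm check of the labels, and the array is called knockout-labelled throughout. Of the other lysyl oxidase genes, Loxl1, which acts on elastic fibres, was higher on the knockout-labelled array with both of its probes, at 0.53 ± 0.21 and 0.60. Lox was at −0.04 ± 0.33. Loxl2 was at −0.02 ± 0.22 with its brighter probe and at −0.52 with another, and Loxl4 was not well above background on either array. The family's median of −0.03 lay at percentile 35.7 of random gene lists matched on signal and turned positive when the arrays were scaled on probes above background on both.

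Digestive enzyme genes of the exocrine pancreas were far higher on the knockout-labelled array, and genes of neutrophil precursors, platelets and basophils were lower. Of 22 pancreas genes, 20 were at least 2-fold higher and none was lower, with a median log2 difference of 3.69, or 12.9-fold. Of 17 neutrophil and granulocyte precursor genes, 12 were at least 2-fold lower and none was higher, with a median of −1.62. Lists of T cell markers, regulatory T cell genes and STAT3 pathway genes did not stand apart from random lists in the main calculation, while Th1 and Th2 cell genes lay below them. Among all 13716 genes measured, 352 were at least 2-fold higher and 310 at least 2-fold lower on the knockout-labelled array, 4.83% together.

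The pancreas genes had the largest differences of any list. Reg1, encoding a secreted protein of acinar cells, was higher by 4.83 ± 0.23 on the log2 scale, with a signal of 190 on the wild-type array and 7790 on the knockout-labelled array. Clps, the cofactor of pancreatic lipase, was higher by 4.49 ± 0.21, the trypsinogen gene Prss1 by 4.24 ± 0.25 and the bile salt-activated lipase gene Cel by 4.21 ± 0.21. The other probes of Clps and Prss1 were at 3.67 and 2.54. Sycn, a zymogen granule gene, Cpa1, a carboxypeptidase gene, and Ctrb1, a chymotrypsinogen gene, were higher by 4.19, 4.08 and 4.07. Of the insulin genes, Ins2 was at 0.41, and Ins1, above background on the knockout-labelled array alone, was higher by at least 0.41. The list median exceeded all 10000 matched random lists (percentile 100). Most pancreas genes, 20 of 22, were also well above background on the wild-type array. Trypsinogen, chymotrypsinogen and elastase genes are close relatives, so their probes may share signal.

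Genes of neutrophils and their marrow precursors were lower on the knockout-labelled array, and all 17 measured members were below 0. Camp, encoding the antimicrobial peptide cathelicidin, differed by −2.64 ± 0.20, and its other probe by −3.14. Ltf, encoding the granule protein lactoferrin, differed by −2.60 ± 0.20, Chil3, a chitinase-like gene, by −2.53 and the myeloperoxidase gene Mpo by −2.41. Lcn2 (−2.28) and Ctsg (−2.14), both granule protein genes, were also among the 12 lower members. Cxcr2, the chemokine receptor of mature neutrophils, was at −0.18 and the gelatinase gene Mmp9 at −0.26. The list median was 3.07 times lower and lay at percentile 0 of random lists.

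Megakaryocyte and platelet genes were lower as well, with 7 of 11 at least 2-fold lower and a median of −1.19 (percentile 0). Treml1, a platelet granule receptor gene, differed by −1.91 ± 0.20, the von Willebrand receptor gene Gp1ba by −1.86, and the platelet chemokine genes Ppbp and Pf4 by −1.83 and −1.78. Of 6 mast cell and basophil genes, 3 were at least 2-fold lower, and the list median was −0.87 (percentile 0.010), or −0.69 with genes above background on 1 array alone held at their bound. The basophil protease genes Prss34 and Mcpt8 were above background on the wild-type array alone, at least 5.52-fold and 2.10-fold higher there. Hdc, the enzyme gene for histamine synthesis, differed by −1.42, and Kit, the stem cell factor receptor gene, by 0.58. With probes above background on both arrays alone, 4 of these genes remained measured and the median was −0.15, inside the random range. That filter removed Prss34 and Mcpt8 because they were dim on the knockout-labelled array, so it describes only the genes left.

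Erythroid genes had a median of −0.43 (percentile 0.135), with 4 of 19 at least 2-fold lower. These were the beta-globin gene Hbb-b2 at −1.73, the transcription factor genes Tal1 and Gata1 at −1.15 and −1.12, and the blood group gene Rhd at −1.09. Klf1, an erythroid transcription factor gene, was at 0.73. Proliferation genes had a median of −0.50 (percentile 0), and 18 of 20 were below 0. Among them only the mitotic kinase gene Aurka passed 2-fold (−1.02), followed by Birc5 at −0.92, Rrm2 at −0.76 and Ccnb1 at −0.76. The 3 probes of Birc5 ranged from −0.92 to −0.17 and those of Ccnb1 from −0.76 to −0.08.

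Interferon-stimulated genes were mostly lower on the knockout-labelled array, with a median of −0.59 (percentile 0) and 13 of 16 below 0. The antiviral oligoadenylate synthetase gene Oas1a differed by −1.01 ± 0.20 and Usp18, a negative regulator of interferon signalling, by −0.92. Oasl1, of the same family as Oas1a, was at 0.501 times the wild-type level. Ifi44 went the other way, at 1.04 ± 0.21. Th1 and Th2 cell genes had a median of −0.38 (percentile 0.340), and none of the 14 passed 2-fold. In that list the interferon gamma gene Ifng was at −0.90, Il18r1 at −0.77 and Il4 at −0.68.

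Medians of stromal and fat genes lay on the higher side by small amounts, on the same array where pancreas genes were 12.9-fold higher. Extracellular matrix and fibroblast genes had a median of 0.30 (percentile 99.98), with Bgn, a small proteoglycan gene, at 1.27 ± 0.28 and Col1a1 at 0.93, while Mgp was at −0.71. Eln, the elastin gene, was above background on the knockout-labelled array alone and at least 1.89-fold higher there. The list median was 0.07 with normexp background correction. Of these 17 genes, 12 were above 0 and 1 passed 2-fold. Endothelial genes had a median of 0.29 (percentile 99.92), with 6 of 11 above 0 and 5 below, and none passed 2-fold. Among them Tek was at 0.73, Cdh5 at 0.67 and Pecam1 at 0.40, and Lyve1, above background on the wild-type array alone, was at least 1.40-fold higher there. Adipose and mesothelium genes had a median of 0.32 (percentile 99.69), with the adipocyte genes Cfd, Plin1, Adipoq and Cidec at 1.01, 0.76, 0.74 and 0.62, and of 12 genes 7 were above 0, 5 below and 1 at 2-fold. The mesothelium genes Msln and Upk3b were at −0.19 and −0.06.

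Among resident immune cells, B cell genes had a median of −0.02, close to 0 but high for genes of their signal level (percentile 99.6). Fcer2a, the low-affinity IgE receptor gene, was higher by 1.13 ± 0.21, Cd79a was at 0.75, Cd22 at 0.68 and the complement receptor gene Cr2 at −0.43, and 1 of 17 passed 2-fold. Macrophage genes had a median of 0.05 (percentile 99.5) with none of 15 at 2-fold, and Cd5l was at −0.86, Treml4 at 0.85, Cd163 at 0.73 and Axl at 0.61. Dendritic cell genes had a median of 0.18 (percentile 99.5). Xcr1, the receptor gene of cross-presenting dendritic cells, was above background on the wild-type array alone and at least 7.08-fold higher there. Itgax and Cd209a were at 0.92 and 0.73, and Siglech was at −0.58 with its brighter probe and 0.18 with the other. The medians of these 3 lists changed sign under at least 1 other scaling, and their place above the random lists was lost under other settings, for dendritic cell genes in 7 of 13.

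The STAT3, Th17, regulatory T cell and T cell marker lists did not stand apart in the main calculation. Th1 and Th2 cell genes, given above, did (median −0.38, percentile 0.340). STAT3 pathway and target genes had a median of −0.09 (percentile 83.2), with 1 of 28 at least 2-fold higher and 1 at least 2-fold lower. Without members of other lists it lay above the random range (percentile 97.7, median −0.03), and its median was positive under 4 of 6 other scalings. The higher was the adhesion molecule gene Icam1 (1.92 ± 0.24) and the lower was Lcn2, which the neutrophil list also holds. Birc5 and Junb were at −0.92 and 0.78, and Stat3 itself was at −0.16 with its brighter probe and 0.54 with the other, so its direction is open. Th17 cell genes had a median of 0.11 (percentile 91.6), with Il21 at −0.72, Irf4 at 0.59, Ccr6 at −0.31 and Ahr at 0.25. Regulatory T cell genes had a median of −0.10 (percentile 28.7), with Tnfrsf4 at −0.81, Nrp1 at 0.63, Tnfrsf18 at −0.48, Il2ra at −0.45 and Foxp3, the lineage's transcription factor gene, at −0.35. T cell genes had a median of −0.11 (percentile 86.4), and the adaptor gene Lat was the only member of 22 at 2-fold, at −1.77 ± 0.20. Cd3d was at −0.46 and Tcf7 at 0.37.

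Other immune lists also lay inside the random range in the main calculation. NK and cytotoxic cell genes had a median of 0.09 (percentile 91.3), with the inhibitory receptor gene Klrg1 at −1.07, Ncr1 at 0.72, Klrk1 at 0.69 and the granzyme gene Gzma at −0.58. Monocyte genes had a median of −0.14 (percentile 48.4), with Chil3 the only member at 2-fold and F13a1 at −0.87. Plasma cell genes had a median of 0.05 (percentile 94.0), with Slamf7 at 0.44 and Sdc1 at 0.43, and Tnfrsf13b at 0.48 with its brighter probe and −0.09 with the other. That list lay above the random range with quantile normalization (0.28), the loess trend removed (0.30) and the deposited value table (0.29). Germinal centre genes had a median of 0.07 (percentile 76.9), with Gcsam at −0.56 and S1pr2 at 0.42. Lymphoid stromal chemokines had a median of 0.05 (percentile 96.4), with Cxcl12 at 0.67 and Cxcl13 at 0.42. Cytokines and chemokines of inflammation had a median of −0.08 (percentile 56.0), with Il1b at −0.64, Ccl4 at −0.60 and Tnf at 0.57.

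Smooth muscle genes had a median of −0.03 (percentile 64.8), with the desmin gene Des at 1.13 and Acta2 at −0.30. Immediate early genes had a median of 0.01 (percentile 67.8), with Ier2 at 1.23, Junb at 0.78 and Fos at 0.49. Heat shock and unfolded protein response genes had a median of −0.20 (percentile 76.5), with the mitochondrial chaperone genes Hspd1 and Hspe1 at −0.79 and −0.73 and Sdf2l1 at 0.65. With the median of a gene's probes in place of the brightest, that median was 0.14 and lay above the random range, and it was also positive with quantile normalization, loess and the deposited table. Lysine deacetylases had a median of −0.15 (percentile 47.5), led by Hdac6 at −0.75 and Hdac7 at −0.62. Ribosomal protein genes had a median of −0.54 (percentile 2.73), with Rpl4 at −1.42 and Rps18 at −0.97 with its brighter probe and −0.08 with the other, and the median was −0.04 with quantile normalization but lay below the random range with the median of a gene's probes (−0.50). Housekeeping genes had a median of −0.20 (percentile 82.5), with Ywhaz at 1.13 and B2m at −0.61. The Y-linked genes Uty, Ddx3y and Eif2s3y were above background on both arrays, at 0.52, 0.16 and −0.37, and Xist was not measured above background on either. Of the 18 lists inside the random range, 15 had medians that changed sign under at least 1 of 6 other scalings.

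Several genes outside the lists also differed by large amounts. Cela3a, a pancreatic elastase gene, was higher by 4.39 ± 0.20 (other probe 3.71), Dmbt1, a secreted scavenger receptor gene of epithelia, by 4.30, and the netrin receptor gene Unc5a was 18.3-fold higher. Gdpd3, encoding a phosphodiesterase of lysophospholipids, had the lowest value, −6.03 ± 0.32 or 65.5 times lower, from a single probe with signals of 5088 and 112. Cybb, the catalytic subunit of the phagocyte oxidase, was at −2.83 and the integrin-like gene Itgb2l at −2.76. Cebpe, a transcription factor gene of granulocyte maturation, was at −2.49, Ms4a3, a marker of granulocyte-monocyte precursors, at −2.48, and Wfdc21 at −2.41.

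Some genes were well above background on 1 array alone, 495 on the knockout-labelled array and 187 on the wild-type array. Trim12a, of an antiviral restriction factor family, was at least 184-fold higher on the knockout-labelled array with its brighter probe. Its other probe had a log2 difference of 6.21, for which no bound was computed. Ifi202b, an interferon-inducible gene whose level differs between inbred mouse strains, was at least 47.7-fold higher there with its brighter probe. The RNA export gene Nxf3 was at least 11.5-fold higher and Ifi44l, a relative of Ifi44, at least 9.11-fold. The pancreatic phospholipase gene Pla2g1b was higher by at least 3.47 on the log2 scale. On the wild-type array the pheromone receptor gene Vmn1r174 was at least 24.0-fold higher, Jhy at least 14.6-fold, Hal, the histidine ammonia-lyase gene, at least 6.10-fold and Dppa2 at least 5.58-fold.

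**Figure D1:**
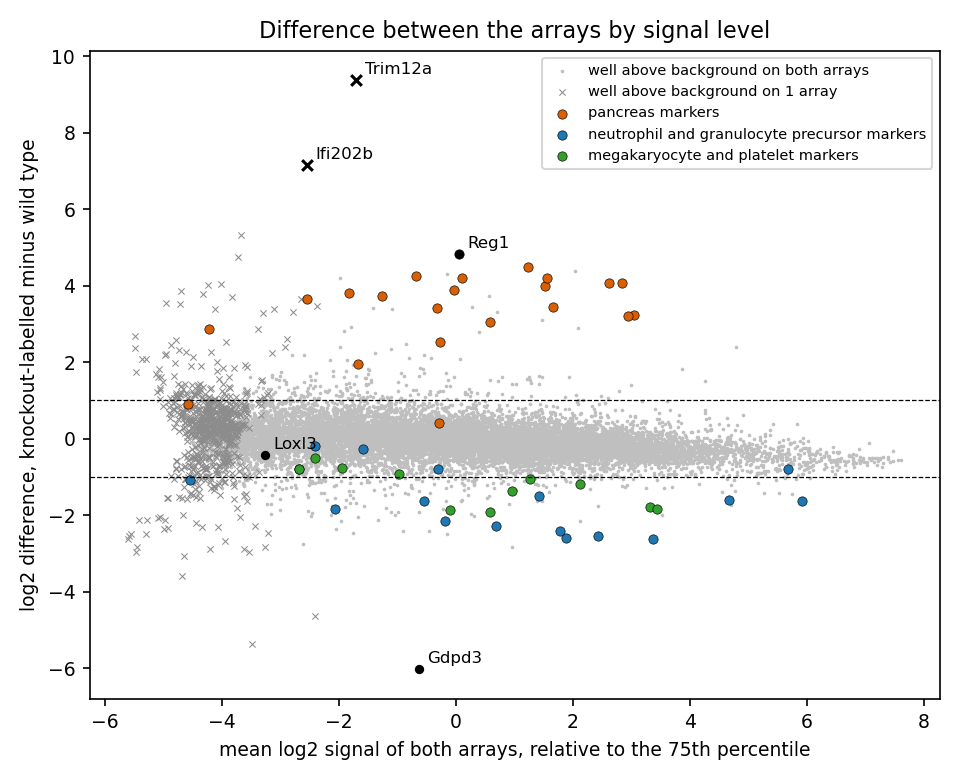
Each point is a gene, with its mean scaled log2 signal on the x axis and its log2 difference, knockout-labelled minus wild-type array, on the y axis, and dashed lines mark 2-fold. Crosses are genes well above background on 1 array alone, drawn at their measured difference although only a bound is known. Genes of the coloured lists are filled circles even where they are above background on 1 array alone. Of 22 pancreas genes 20 lie above the upper line, and 12 of 17 neutrophil genes lie below the lower.

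**Figure D2:**
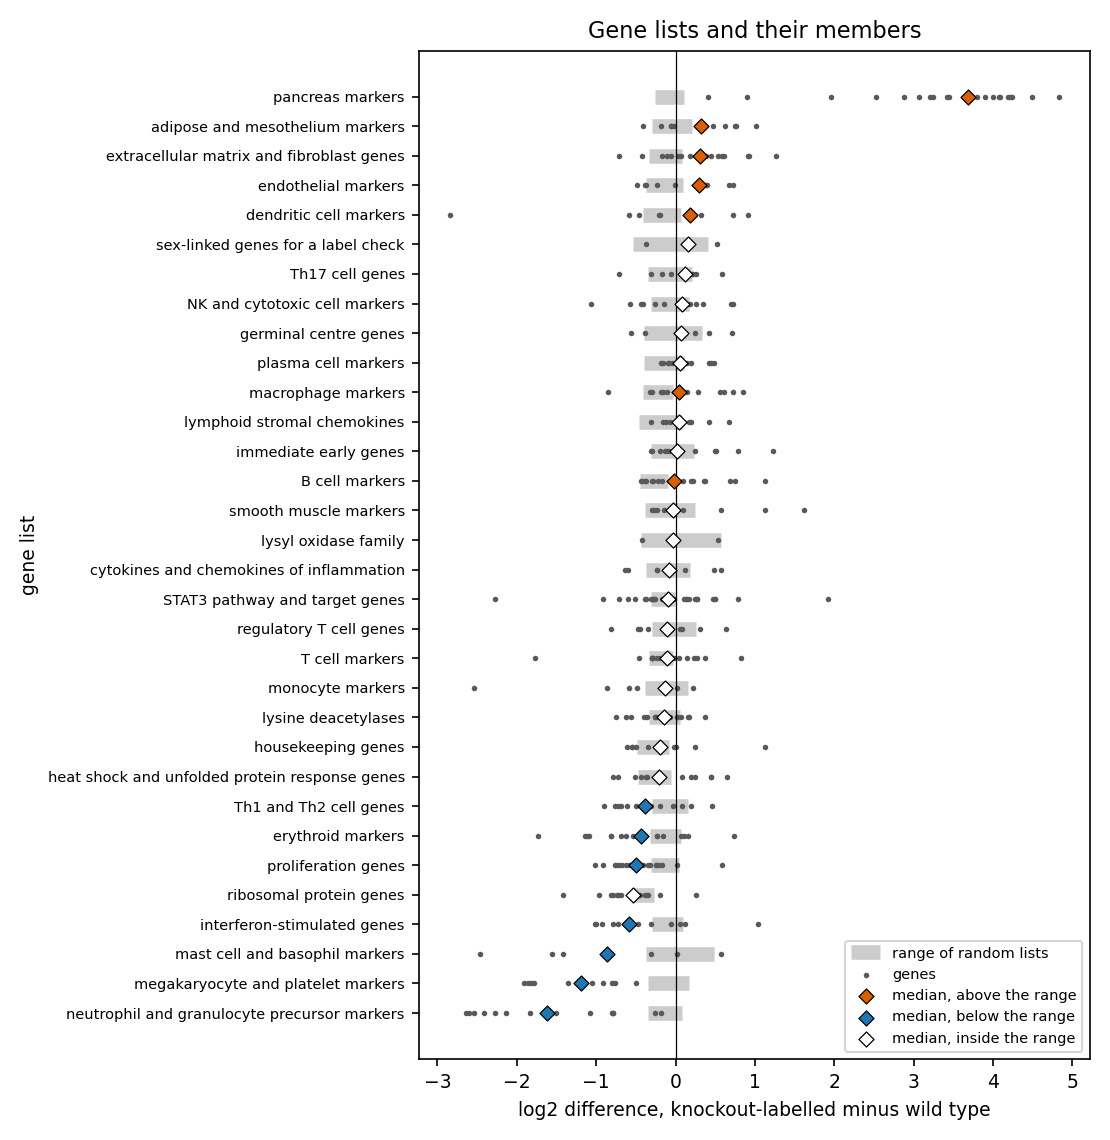
Each row is a gene list, with points for its genes, a diamond for its median and a grey bar for the central 95% of medians of 10000 random lists matched on signal, on a log2 axis of knockout-labelled minus wild-type array. The pancreas median is at 3.69 and the neutrophil median at −1.62, and medians near 0 change sign under other scalings.

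Of the 32 lists, 7 lay above and 7 below the central 95% of matched random lists. By chance 1.6 would, if genes within a list varied independently. Markers of the same cell type can move together, so this number may be too low. Of all genes at 2-fold, 53.2% were higher on the knockout-labelled array. Scaling on each array's median gave 293 higher and 418 lower genes (41.2% higher). Normexp background correction left 151 higher and 186 lower genes (44.8% higher). Scaling on the 75th percentile of probes above background on both arrays, chosen after the data were seen, moved the median of all genes by 0.15 and gave 517 higher and 212 lower genes (70.9% higher). Across genes the arrays correlated with a Pearson r of 0.977 and a Spearman rho of 0.980, and genes are not independent replicates. The log2 difference was lower for brighter genes, with a median of 0.0056 in the dimmest 10% of genes and −0.35 in the brightest 10%. Matching of random lists on signal, fixed before the data were examined, takes account of such a trend. Of 58 higher genes with 2 or more probes above background, 47 were higher with every probe and 16 at least 2-fold with every probe, and of 39 such lower genes the counts were 28 and 6.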

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

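The comparison with named probes was chosen after the result was seen. Probes whose accession matched no gene symbol were left out of the counts of genes, and many of them carried signal. Of 5238 such probes well above background on at least 1 array, 256 were at least 2-fold higher and 206 at least 2-fold lower on the knockout-labelled array. Together these made 8.82% of the unnamed probes, against 5.16% of 17535 named probes above background. No explanation was tested for the higher share.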

How the results depend on the processing

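Scaling on probes above background on both arrays, the left-out pancreas, acinar and islet or blood cell genes and the 2-probe rule were tests chosen after the data were seen. The Loxl3 difference moved by less than its software error under 6 other scalings, from −0.53 to −0.28, and the other alternatives cannot move a gene with 1 probe above background on both arrays. Counts of higher and lower genes stayed within 1.5 times the main counts of 352 and 310 under the other scalings, and without the pancreas, further acinar and islet genes (326 higher) or without the neutrophil, basophil, platelet and erythroid genes (284 lower). They moved further to 151 and 186 with normexp, 613 and 699 with no filter on dim probes, 572 and 597 with the median of all probes, 1103 and 1300 at 1.5-fold, 127 and 90 at 3-fold, and 16 and 6 among genes with 2 or more probes all passing 2-fold, where fewer genes could pass. No list went to the opposite side of the random lists. Of the 14 lists apart, 10 stayed apart in all 13 alternatives. B cell genes lay inside the random range with normexp (−0.114), with the median of all probes (−0.0230) and against unmatched random lists (−0.0230), and macrophage genes against unmatched random lists (0.0489). Dendritic cell genes lay inside it with quantile normalization (0.0984), loess (0.122), normexp (−0.00807), the deposited value table (0.0980), the median of detected probes (0.176), the median of all probes (0.0457) and unmatched random lists (0.176). Mast cell and basophil genes did so with probes above background on both arrays (−0.148). That filter left 4 genes, without those dim on the knockout-labelled array. The list was at −0.311 with no filter or the median of all probes. Among lists that stayed apart, medians moved by more than 1.5 times for extracellular matrix genes with normexp (0.0713), adipose genes with normexp (0.186), endothelial genes with the median of detected probes (0.176), interferon-stimulated genes with loess (−0.388), and Th1 and Th2 genes (−0.236) and erythroid genes (−0.289) scaled on probes above background on both. Ribosomal protein genes moved from −0.541 to −0.0420 with quantile normalization, −0.0510 with loess and −0.0390 with the deposited table. Other lists came to stand apart: plasma cell genes with quantile normalization (0.285), loess (0.304) and the deposited table (0.285), STAT3 genes without members of other lists (−0.0253), heat shock genes with either probe median (0.144), and ribosomal protein genes with no filter (−0.541), either probe median (−0.499) and unmatched random lists (−0.541). The cause was not tested. Of the values of named genes under these settings, 1402 moved by less than the software's error, some under settings that cannot move a gene with 1 probe, and 176 by more, and no gene at 2-fold changed sign. Leaving out saturated probes removed nothing and says nothing about stability. No array could be left out and no other split of the samples exists with 1 array per group. No paired analysis was possible because each group holds 1 array. Signal over background limits the dimmest genes, since 682 genes were above background on 1 array alone.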

Other observations

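The counts of pancreas genes on the wild-type array, the comparisons of the neutrophil list with B cell genes and of precursor with mature neutrophil genes, and the count expected from repeated spots were tests chosen after the result was seen, and so were the genes and symbol families named first here.

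Gene families sharing the letters of their symbols gave a further view. Of 344 families with at least 6 measured genes, 16 lay above and 22 below the central 95% of matched random lists. By chance 17.2 in all would, if genes within a family varied independently. Insulin-like growth factor binding protein genes (Igfbp) had a median of 0.79 over 6 genes, with Igfbp4 at 1.64 and Igfbp7 at 1.37. Apolipoprotein L genes (Apol) had a median of −0.89 over 7 genes, with Apol11b at −2.00 and Apol10a, above background on the wild-type array alone, lower by at least 1.99, and oligoadenylate synthetase genes (Oas) had a median of −0.70 over 7 genes. These medians kept their sign under all 6 scalings, from 0.69 to 0.93, −0.98 to −0.74 and −0.79 to −0.47. The amylase genes Amy1 and Amy2a5, products of acinar cells, were at 2.90 and 2.39. Prg3, an eosinophil granule gene, was at −1.78. The restriction factor gene Trim34a was at 3.10 with its brighter probe and 0.65 with the other.

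Pancreas genes were higher on the knockout-labelled array, and a candidate explanation is pancreatic tissue collected with the spleen, which it adjoins. A separate list of further acinar genes, 10 of 16 measured and 7 of these above background on the wild-type array, had a median of 1.26 (percentile 100), or 1.25 with bounds, and among the most abundant acinar genes Cpa1 had a signal of 41237 and Ctrb1 of 35052. A trend of the difference with signal level is argued against, since the pancreas median was still 3.64 with the loess trend removed. Of the islet list only 2 genes were measured, Sst and Pcsk2, with a median of −0.68, and the insulin genes Ins2 and Ins1 of the pancreas list were at 0.41 and at least 0.41, too few genes to tell whether islets came along. An effect of the genotype on these genes in spleen cells cannot be told apart from carried tissue with 1 array per group, and 20 of the 22 pancreas genes were above background on the wild-type array too.

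Genes of neutrophils, basophils, platelets and erythroid cells were lower on the knockout-labelled array. For the neutrophil genes dilution by pancreatic RNA is argued against, since it would lower other spleen cells alike and the neutrophil median lay 1.60 below that of B cells (difference −1.60, random range −0.14 to 0.41), and a trend with signal is too, with the neutrophil median at −1.36 after loess. Less blood left in the tissue stays open, since mature blood neutrophil genes were low too (median −0.53, percentile 0.630) and platelet and erythroid genes were not tested against it; precursor genes (median −2.28) lay below the mature genes by −1.75 (random range −0.29 to 0.49), but both lists were written with values in view. Fewer haematopoietic progenitors stay open, since 13 progenitor genes had a median of −0.23 (bootstrap range −0.37 to 0.26), and that range reaches below the random range, which starts at −0.31. An effect of the genotype and differences between single animals stay open, untested here, and the erythroid gene Klf1 (0.73) went the other way.

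Trim12a, Ifi202b, Gdpd3 and other genes lay far from the rest. Error of single spots is argued against as the whole cause, since repeated spots gave 73.6 genes expected at 2-fold against 662 found and, from 3 spots, 15.8 at 4-fold against 66 found outside the pancreas, acinar and islet lists and the fixed neutrophil, basophil, platelet and erythroid lists, though a single-probe gene such as Gdpd3 stays open to it. Differences in strain background are a candidate explanation, because knockout lines may carry stretches of another strain. Among the 100 measured genes nearest to Loxl3, 9 were at 2-fold (other windows 1 to 14, median 4). Of these, 3 belong to the pancreas and further acinar lists. Reg3b, of the same symbol family as Reg1 but outside those lists, is also among them (higher by at least 2.61). The count therefore does not settle it. Of the 66 genes at 4-fold or more, 5 had another such gene of a different symbol family within 5 measured genes on either side. The random range was 0 to 8. Genes sharing the first 3 letters of their symbols counted as the same family. Trim12a and Trim34a, both among the 66, therefore could not count for each other. The 5 include Pdia2 and the trypsinogen gene Prss2, so the count mostly restates the pancreas pattern. It leaves a strain difference and an effect of the genotype open.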
